A study of Caenorhabditis elegans with 2 samples.

How the data were processed

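LIN-35 was profiled by ChIP-seq in whole, mixed-sex L1 larvae of strain YL409, with 1 group of 2 biological replicates and DNA fragments of 150 to 350 bp per the labels. The labels give lin-35 as the antibody target and describe the bound protein as a GFP fusion, so whether the precipitation used the tag is not given in the sources used here. Replicate numbers were taken from the labels.

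The data are 8 deposited peak lists, 4 each in the ce11 and ce10 builds: 1 per replicate, 1 pooled over both replicates, and 1 that passed an IDR threshold. Per the submitters' deposited file manifest, each replicate list was made from that replicate's alignment and a control alignment, the pooled list from both replicates and a control, and the IDR list from the pooled and both replicate lists. Peaks were thus called per replicate and on pooled replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control was not analysed here. The deposited signal value of each peak is the authors' and was used only to rank, filter or describe peaks within a list. The deposited lists also hold a −log10 q-value per peak. It reached its highest value, 3.92, in all IDR peaks of ce11, so it could not rank them. In each build the IDR list was tested on the files to be exactly the strongest peaks of the pooled list by signal, 3838 of 30000 in ce11. The lists labelled as peaks and background hold weak peaks too, and the pooled and replicate 2 lists both end at 30000. In replicate 1, 95.4% of peaks had the same width of 264 bp, in replicate 2 93.8% had 316 bp and in the pooled list 92.7% had 324 bp, so widths of single peaks were not interpreted. Counts of reads are not part of these lists, the depth is unknown, and no interval that needs it was given. Intervals over peaks or genes cover counting error only.

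Coordinates are ce11, printed from 1. All ce11 peaks lay within the chromosome lengths of the WBcel235 reference, which is the same assembly. Genes came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. The ce10 lists were used only for counts, overlap and rank correlation, and no coordinate was converted. A gene was called bound when the summit of an IDR peak lay within 500 bp of the 5′ end of its gene record, which held for 2722 genes (13.6%). Genes with neighbouring starts can share a peak, so genes are not independent, and gene records can start downstream of the true promoter, as in trans-spliced genes. The position of a summit was assigned to coding exon, 5′ UTR, 3′ UTR, intron or between protein-coding genes, in that order.

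Before the data were examined, 19 gene lists, the tests and the rule for named genes were fixed. The lists were DREAM complex, other synMuv, cell cycle regulators, DNA replication, mitosis and chromosome segregation, DNA repair and damage checkpoint, meiosis, P granule and germline, small RNA pathways, ribosomal proteins, proteasome subunits, histones, neuron markers, muscle markers, intestine markers, cuticle collagens, chemoreceptors, sperm proteins, and homeobox and nuclear receptors. The symbols cdc-45, pold-1, rad-54, rde-3 and cde-1 did not match the annotation and were left out. The named genes were those nearest to the 15 strongest IDR peaks, the up to 3 bound genes of each list with the strongest promoter peak, and always lin-35, unc-119 and the DREAM genes. Other genes that share a peak with a named gene were named after their values were seen.

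Replicate overlap was the share of the 3838 strongest nuclear peaks of 1 replicate that overlapped the other by at least 1 bp, tested by 1000 circular shifts along each chromosome. Shares at gene starts were tested by shifting the summits in the same way. Chromosome shares were tested by exact binomial tests and list enrichment by Fisher's exact test with conditional odds ratios, with Benjamini-Hochberg adjustment over chromosomes and over lists. Peak strength was the median rank of the bound genes of a list against that of the other bound genes, for the 17 lists with at least 5 bound genes, by an exact permutation test below 10 bound genes, in which every choice was counted, and by a permutation test with 100000 resamples otherwise. Motifs on either strand within 50 bp of the summit were compared with a window 500 bp away on a random side by an exact McNemar test, adjusted over both motifs. The interval of Spearman's rho came from the Fisher transformation.

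Alternatives were the ce10 build, the stronger 1919 IDR peaks, the 3838 strongest peaks of each replicate alone in place of the IDR list, other overlap rules, windows of 250 and 1000 bp, the 5′ end of any transcript, nearest start only, leaving out 3615 candidate downstream operon genes (another gene on the same strand ending within 500 bp upstream), chromosome length as background, windows of 100 bp for motifs, reversed motifs, and weaker pooled peaks as the motif control. Added after seeing the data were a peak strength test with each shared peak counted once, a background of the 7409 genes with any pooled peak, and the motif comparison stratified by GC content in 10 bins, summarised by the Mantel-Haenszel odds ratio. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used, with random seed 1.

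The statistics for replicate overlap, shares at gene starts, list enrichment, peak strength and motifs were tested on simulated data; the binomial tests, the Mantel-Haenszel odds ratio and the interval of Spearman's rho were not. Of simulated lists with odds of binding raised over 19973 genes 100% were called, at a median odds ratio of 4.93, and 1% of random lists were. Genes were drawn independently in these simulations, without shared peaks. The shares called therefore do not cover neighbouring genes that share a peak. The exact strength test differed from full enumeration in 0 of 60 small simulated cases. Mitochondrial peaks were left out of all comparisons.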

Results

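Chromatin immunoprecipitation with sequencing (ChIP-seq) mapped the binding of LIN-35 in whole first-stage (L1) larvae of the nematode Caenorhabditis elegans. LIN-35 is the worm's only Rb-family pocket protein and a subunit of the DREAM complex, a repressor of cell cycle genes. The larvae came from strain YL409, which carries the transgene vrIs60. That transgene expresses LIN-35 fused to GFP and FLAG from the lin-35 promoter and also holds a working copy of unc-119. There was 1 group, LIN-35 ChIP in L1 larvae, with 2 biological replicates per the labels. No other strain, stage or untagged sample was analysed here, so no comparison between groups was possible, and the comparisons below set peaks against the genome, gene lists against other genes, and replicate 1 against replicate 2. The values are peak positions and the authors' signal value for each peak. Read depth is unknown.

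The strongest LIN-35 peaks lay just upstream of protein-coding genes. The strongest of the 3838 peaks that passed the authors' irreproducible discovery rate (IDR) threshold lay at rpl-3, a large ribosomal subunit protein (chromosome III, 3867384 to 3867749, ce11, signal 3457), with its summit 284 bp upstream of the gene and between genes. The next lay at cdc-48.1, the AAA ATPase that extracts ubiquitinated proteins (chromosome II, 10563379 to 10563743, signal 3418), at sec-61.G, a subunit of the protein translocon (chromosome V, 10897209 to 10897591, signal 3004), and at dld-1, dihydrolipoamide dehydrogenase (chromosome IV, 14464075 to 14464444, signal 2708). The 15 strongest peaks also included those of tba-2 (alpha-tubulin, signal 2549), cox-5A (a cytochrome c oxidase subunit, signal 2237), rpl-35 (signal 2227) and eef-2 (translation elongation factor, signal 2032), and those nearest to eelo-2, tasp-1, fipr-17, F48A11.4, syf-3, citk-2 and Y53F4B.11 (signals from 2616 to 2007). The peaks of eef-2, fipr-17 and Y53F4B.11 were shared with clsp-1, Y48A6B.3 and Y53F4B.9. All 15 summits lay between protein-coding genes and within 500 bp of a gene start. The IDR list has the 3838 strongest of the 30000 pooled peaks, a signal of 56.0 or more, and a median signal of 125. The deposited IDR list of the older ce10 build held 4839 peaks, 1001 more. The pooled lists of both builds held 30000 peaks at a median signal of 15.2. The ce10 IDR list reached down to a signal of 41.8, so the counts differ in where the pooled list was cut. Why the cutoffs differ is not given in the sources used here.

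The replicates bound largely the same places. Of the 3838 strongest peaks of replicate 1, 2928 (76.3%) overlapped 1 of the 3838 strongest of replicate 2 by at least 1 bp, and 2932 (76.4%) did in the other direction. Shifting replicate 1 along the chromosomes gave 2.00% on average and at most 2.68% (permutation test, 1-sided, 1000 shifts, p = 0.000999, the smallest they can give). Of the IDR peaks, 3732 (97.2%) had a peak in both replicate lists, and over these the ranks by signal correlated with a Spearman rho of 0.798 (95% interval 0.786 to 0.810, across peaks, which are not independent replicates). The IDR list was itself made from the pooled and both replicate lists. That share and the rho therefore partly reflect how its peaks were chosen. The 15 strongest peaks ranked from 1 to 22 in replicate 1 and from 1 to 16 in replicate 2. Among them, rpl-3 ranked 1 in both, cdc-48.1 ranked 4 and 2, tba-2 ranked 2 and 6, and Y53F4B.11 ranked 22 and 13. Replicate 1 had the lower median signal, 4.65 against 11.6, over 23861 and 30000 peaks. The scale of the signal differs between lists, so these medians show no difference in binding. Over the 3732 matched IDR peaks the pooled signal followed replicate 2 more closely (rho 0.967) than replicate 1 (rho 0.873). The ranks in the IDR list thus lean on replicate 2, and replicate 2 alone is the less independent check of them.

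**Figure D1:**
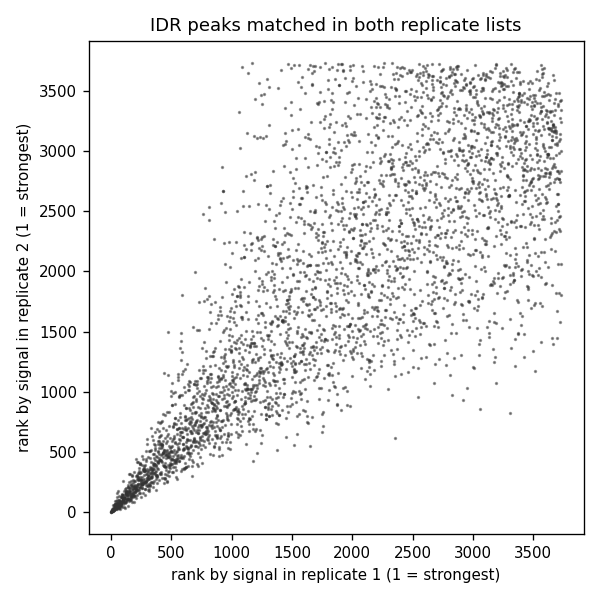
Rank by the authors' signal in replicate 1 (x axis) and replicate 2 (y axis) of the 3732 IDR peaks matched in both lists, each point 1 peak and rank 1 the strongest. The strongest peaks lie near the diagonal and the spread grows towards the weaker ones, with a Spearman rho of 0.798.

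Binding concentrated at the starts of protein-coding genes. The summits of 2136 of 3838 IDR peaks (55.7%) lay within 500 bp of the 5′ end of a protein-coding gene, against 18.6% on average and 20.6% at most after circular shifts (permutation test, 1-sided, 1000 shifts, p = 0.000999, the smallest they can give). Of those 2136 summits, 1920 (89.9%) were upstream of the nearest start, and the median distance of these 1920 was 166 bp. Between protein-coding genes lay 2871 summits (74.8%, where 37.3% of the genome lies), in introns 749 (19.5%, genome 33.3%), in 5′ UTRs 153 (3.99%, genome 1.43%), in 3′ UTRs 39 (1.02%, genome 3.32%) and in coding exons 26 (0.677%, genome 24.6%). The other 1702 peaks (44.3%) had no protein-coding start within 500 bp. Among the stronger 1919 IDR peaks the share at starts was 68.6%.

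Chromosomes III and I held more peaks than their shares of gene starts, and V fewer. Chromosome III had 778 peaks, 20.3% of all (exact 95% interval 19.01 to 21.6) where 13.2% of gene starts lie (1.53 times, exact binomial test, 2-sided, adjusted p = 2.97e-33). Chromosome I had 776, 1.40 times its share of gene starts (exact binomial, adjusted p = 3.47e-22). Chromosome V, which carries large families of chemoreceptor genes, had 552, or 0.575 times its share (exact binomial, adjusted p = 1.46e-57). Chromosome II had 608, 0.917 times (exact binomial, adjusted p = 0.0282), a call lost among the stronger 1919 peaks (adjusted p = 0.365), in replicate 1 alone (adjusted p = 0.198) and, at 1.04 times, against chromosome length (adjusted p = 0.302). Chromosome IV had 639, 1.01 times its share (exact binomial, adjusted p = 0.711). The X chromosome had 485 peaks, 0.924 times its share of gene starts, and did not pass the test (exact binomial, adjusted p = 0.0761). The X chromosome passed it at 0.595 times among the stronger 1919 peaks (exact binomial, adjusted p = 8.98e-14), at 0.715 times against chromosome length (adjusted p = 2.73e-17) and, in replicate 2 alone, at 0.915 times (adjusted p = 0.0438).

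LIN-35 sat at most genes for DNA replication and mitosis. Of 40 replication genes, 34 had an IDR summit within 500 bp of the 5′ end (85.0%, against 13.5% of other genes, odds ratio 36.3, 95% exact interval 15.1 to 106, Fisher's exact test, 2-sided, adjusted p = 2.45e-23). Among them were pcn-1 (the sliding clamp PCNA, signal 1216, rank 95), rfc-4 (a subunit of the clamp loader, signal 1161, rank 107) and orc-5 (origin recognition complex, signal 1120, rank 120). Of 61 mitosis and chromosome segregation genes, 46 were bound (odds ratio 19.7, interval 10.8 to 38.1, Fisher's exact, adjusted p = 5.93e-27), led by top-2 (topoisomerase II, signal 1584, rank 38), knl-3 (kinetochore, signal 959) and hcp-6 (condensin II, signal 841). DNA repair and damage checkpoint genes were bound at 19 of 41 (odds ratio 5.50, interval 2.81 to 10.7, Fisher's exact, adjusted p = 1.29e-06), with mrt-2 (a checkpoint clamp subunit, signal 1191), polh-1 (translesion polymerase eta, signal 1164) and brc-1 (signal 976) in front. Of 34 cell cycle regulators, 11 were bound (odds ratio 3.04, interval 1.34 to 6.50, Fisher's exact, adjusted p = 0.00715), among them wee-1.3 (a kinase that inhibits CDK, signal 1784, rank 24), cyb-1 (a B-type cyclin, signal 1120) and cdk-1 (signal 318). Neighbouring genes shared several of these peaks: top-2 with npp-3, polh-1 with rps-22, rfc-4 with eef-1A.1, hcp-6 with let-630, cdk-1 with iff-1, and cyb-1, 489 bp from its summit, with orc-5. The call for cell cycle regulators was lost within 250 bp (5 of 34, Fisher's exact, adjusted p = 0.293) and when each peak counted only for its nearest start (7 of 34, adjusted p = 0.145).

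Most ribosomal protein and proteasome genes were bound too. Of 81 ribosomal protein genes 70 were bound (86.4%, odds ratio 41.4, interval 21.7 to 86.7, Fisher's exact, adjusted p = 2.91e-48), and of 33 proteasome genes 25 (odds ratio 19.97, interval 8.72 to 51.3, adjusted p = 3.62e-15), with rpn-11 (the deubiquitinase of the regulatory particle, signal 1268), pbs-1 (a core particle subunit, signal 775) and rpn-3 (signal 675) strongest, the last 2 in peaks shared with K08D12.3 and hsp-110. At the ribosomal protein genes the summit lay at a median of 288 bp from the annotated 5′ end, against 182 bp over all 2722 bound genes, and 54 of 70 lay beyond 250 bp. Within 250 bp only 16 of 81 ribosomal protein genes remained bound (odds ratio 2.47, Fisher's exact, adjusted p = 0.00656), and when each peak counted only for its nearest start 43 did (odds ratio 9.74, adjusted p = 1.53e-20).

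LIN-35 also bound genes of its own complex. Of 8 DREAM genes 6 were bound (odds ratio 19.05, interval 3.40 to 193, Fisher's exact, adjusted p = 0.000294): efl-1, the E2F subunit (chromosome V, 16965667 to 16966012, signal 1964, rank 17), lin-35 itself (chromosome I, 5807252 to 5807691, signal 1890, rank 21), lin-54, a DNA-binding subunit (signal 1308, rank 74), lin-9 (signal 1111, rank 123), lin-53, a histone-binding subunit (signal 878, rank 185), and dpl-1, the DP partner of E2F (signal 221, rank 1066). The lin-35 summit lay 181 bp upstream of the gene and the peak was shared with vps-51. The transgene also carries the lin-35 promoter, and whether signal at this peak came from it was not tested. The peaks at lin-54 and lin-53 were shared with rpl-12 and nra-2. No IDR summit lay within 500 bp of lin-37 or lin-52. Both were candidate downstream operon genes, with another gene on the same strand ending within 500 bp upstream. Without such genes 6 of 6 DREAM genes were bound, and within 1000 bp 7 of 8 were. Binding further upstream was therefore not excluded for lin-37 or lin-52. With each peak counted only for its nearest start, 4 of 8 were bound (odds ratio 8.46, Fisher's exact, adjusted p = 0.0130).

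Chemoreceptor, cuticle collagen, sperm protein, and homeobox and nuclear receptor genes were bound less often than other genes. Only 5 of 1277 chemoreceptor genes were bound (0.392%, odds ratio 0.0231, interval 0.00749 to 0.0542, Fisher's exact, adjusted p = 7.40e-74), and the peaks at sri-5 and srd-4 were shared with rsr-1 and usip-1. Cuticle collagens were bound at 6 of 169 (odds ratio 0.232, interval 0.0837 to 0.516, Fisher's exact, adjusted p = 5.27e-05). Their strongest peaks, at col-38 (signal 1226) and col-2 (signal 368), were shared with the ribosomal protein gene rpl-5 and the kinetochore gene ndc-80. Homeobox and nuclear receptor genes were bound at 18 of 332 (odds ratio 0.359, interval 0.210 to 0.578, Fisher's exact, adjusted p = 4.19e-06), ceh-38 (signal 437), nhr-47 (signal 429) and nhr-49 (signal 248) having the strongest peaks, those of ceh-38 and nhr-47 shared with malt-1 and dnj-19. Sperm protein genes were bound at 2 of 72, spe-39, in the peak it shares with the germline gene spn-4, and spe-6, in a peak shared with Y66D12A.21 (odds ratio 0.180, interval 0.0214 to 0.677, Fisher's exact, adjusted p = 0.00597). That call passed in only 3 of 9 alternative settings and was lost in replicate 1 alone (odds ratio 0.390, Fisher's exact, adjusted p = 0.0947).

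The remaining 8 lists did not pass the test (Fisher's exact). Binding was found at other synMuv genes, which like lin-35 have roles in vulval development (5 of 17, odds ratio 2.64, Fisher's exact, adjusted p = 0.112, lin-36, lin-38 and mcd-1 strongest). It was also found at small RNA pathway genes (10 of 46, odds ratio 1.76, Fisher's exact, adjusted p = 0.187, rde-4 strongest at signal 578). It was found at muscle markers (5 of 25, odds ratio 1.59, adjusted p = 0.445, unc-45 strongest at signal 728, Fisher's exact), histones (13 of 72, odds ratio 1.40, adjusted p = 0.379, his-37 strongest at signal 469) and neuron markers (6 of 35, odds ratio 1.31, adjusted p = 0.521, snb-1 strongest at signal 235). It was found at meiosis genes (Fisher's exact, 5 of 32, odds ratio 1.17, adjusted p = 0.839, pch-2 strongest at signal 257), P granule and germline genes (8 of 55, odds ratio 1.08, adjusted p = 0.843) and intestine markers (1 of 24, erm-1, odds ratio 0.275, adjusted p = 0.326). The germline genes with peaks included mes-2, a histone methyltransferase (signal 1384, rank 64), spn-4 (signal 711) and ife-3 (signal 439). The synMuv and small RNA lists passed the test among the stronger 1919 peaks (Fisher's exact, adjusted p = 0.0234 and 0.0285) and within 1000 bp (adjusted p = 0.00732 and 0.00769), and histones did within 250 bp (adjusted p = 0.0253). In replicate 2 alone only 2 of 32 meiosis genes were bound, and the odds ratio turned to 0.424; it also turned below 1 for histones among the stronger 1919 peaks (0.604) and for neuron and muscle markers within 250 bp (0.605 and 0.416).

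**Figure D2:**
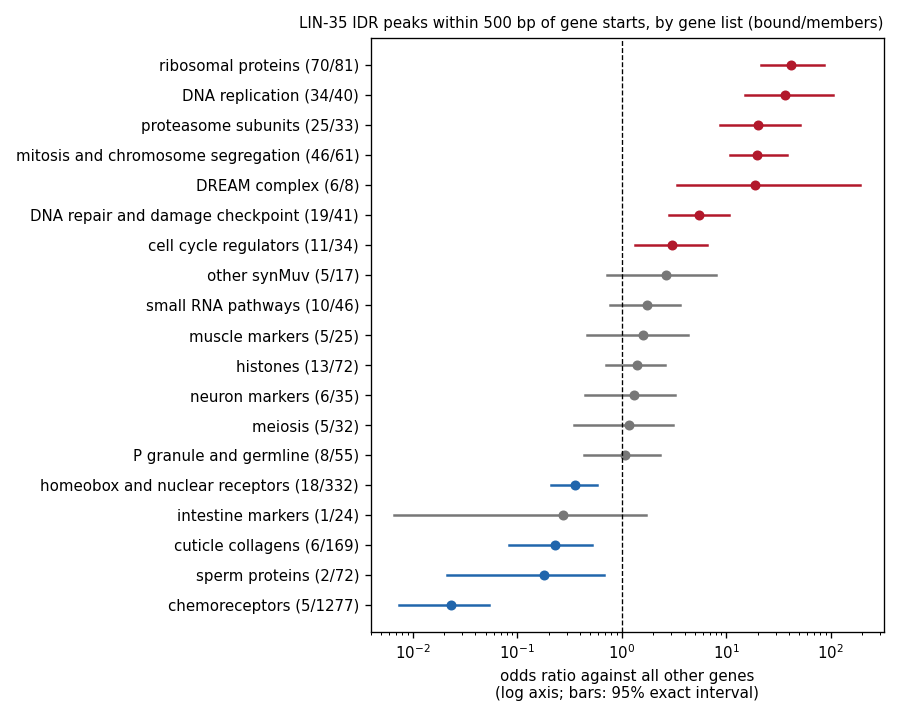
Odds ratio, on a log axis, of a promoter peak in each of 19 gene lists against all other protein-coding genes, with bars for the 95% exact interval, bound and listed genes in parentheses, red for lists bound more often and blue for lists bound less often at adjusted p below 0.05, and grey for the rest. Ribosomal proteins (41.4) and DNA replication (36.3) stand highest and chemoreceptors (0.0231) lowest.

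Peaks at ribosomal protein genes were also stronger than those at other bound genes. Their median rank was 581 against 1348 (permutation test, 2-sided, 100000 resamples, adjusted p = 0.00799), whereas bound histone genes had a median rank of 3031 against 1298 (adjusted p = 0.00408) and homeobox and nuclear receptor genes one of 2581 against 1299 (adjusted p = 0.00975). The 6 bound DREAM genes had a median rank of 98.5 against 1307 and missed the threshold after adjustment over 17 lists (exact permutation test, 2-sided, p = 0.0450, adjusted p = 0.127), as did DNA replication (612.5 against 1317, adjusted p = 0.0892) and meiosis (2862 against 1302, exact permutation test, adjusted p = 0.0903). None of the other lists passed. The call for ribosomal proteins was lost among the stronger 1919 peaks (576 against 779.5, permutation test, adjusted p = 0.369) and within 250 bp, where 16 genes remained bound and the medians were 523 and 1360 (adjusted p = 0.128), and those for histones and for homeobox and nuclear receptor genes were lost in replicate 1 alone (adjusted p = 0.143 and 0.104). The 13 bound histone genes share 8 peaks, and with each shared peak counted once, an alternative chosen after seeing the data, their median rank was 2716 against 1404 and no longer passed (exact permutation test, adjusted p = 0.0743). It was also lost within 1000 bp (permutation test, adjusted p = 0.0782), and that for homeobox and nuclear receptor genes among the stronger 1919 peaks (adjusted p = 0.588).

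The E2F consensus was more frequent at summits than beside them. TTSSCGC, the sequence E2F and DP recognise, occurred within 50 bp of 499 of 3838 summits and in 149 windows of equal length 500 bp away (3.88%, 3.35 times, exact McNemar test, 2-sided, adjusted p = 5.96e-48). It was present at 21 of 34 peaks of DNA replication genes and 26 of 46 of mitosis genes, at 4 of 19 of DNA repair genes, at 0 of 6 of DREAM genes and at 3 of 67 of ribosomal protein genes. Its reversed sequence CGCSSTT, a control of equal composition, was also more frequent at summits (8.36% against 1.49%, exact McNemar, adjusted p = 6.06e-47). TTYGAA, the CHR sequence bound by LIN-54, was less frequent at summits (946 of 3838, 24.6%) than 500 bp away (1240, 32.3%, 0.763 times, exact McNemar, adjusted p = 2.99e-13), as was its reversed sequence AAGYTT (7.58% against 19.4%). The difference for TTYGAA did not pass the test among the stronger 1919 peaks (31.4% against 31.6%, exact McNemar, adjusted p = 0.946) or against weaker pooled peaks (0.979 times, Fisher's exact p = 0.485). It turned to a higher frequency when peaks at gene starts were compared with weaker peaks at gene starts (30.7% against 25.5%), also within bins of GC content (common odds ratio 2.24, 95% interval 1.97 to 2.55), alternatives chosen after seeing the data. For AAGYTT that odds ratio was 0.874 (95% interval 0.728 to 1.05). TTYGAA was present at 22 of 34 peaks of DNA replication genes, 27 of 46 of mitosis genes and 13 of 19 of DNA repair genes. It was at 4 of 6 peaks of DREAM genes and 14 of 67 of ribosomal protein genes, against 30.9% over all bound genes. Differences in TTYGAA between lists were not tested. The median GC content was 47.5% at summits and 35.6% at positions 500 bp to the right.

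**Figure D3:**
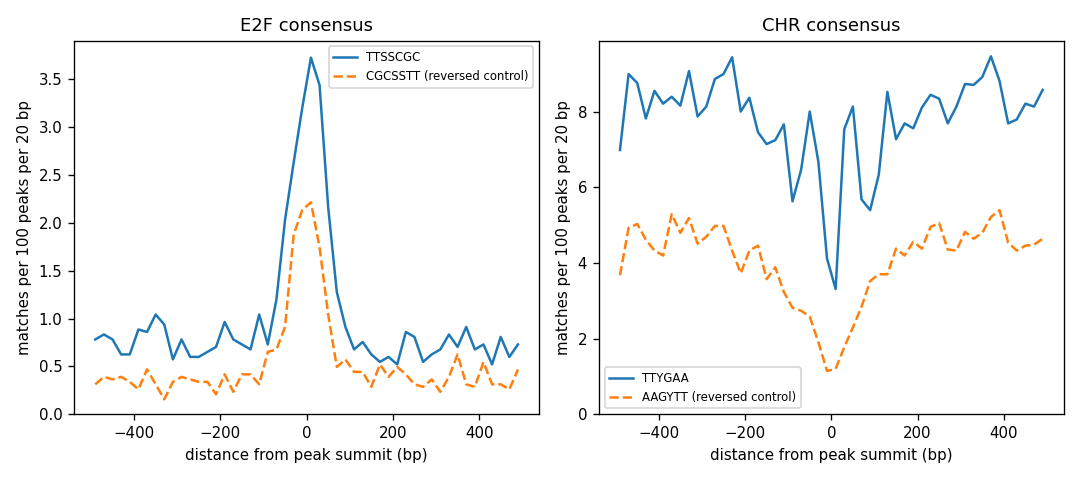
Matches per 100 IDR peaks in bins of 20 bp (y axis) against distance from the summit in bp (x axis), for the E2F consensus (left) and the CHR consensus (right), with the reversed sequence as a dashed line. TTSSCGC reached 3.73 matches in the bin starting at the summit, and TTYGAA fell to 3.31 there with 8.13 in the bin starting at 40 bp.

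Both genes that the transgene carries had weak peaks inside them. At lin-35 the strong promoter peak (signal 1890) was followed by 11 weak pooled peaks inside the gene, with signals from 13.1 to 39.3, of which none reached the IDR list. The gene unc-119, needed in neurons and used as the marker of transformation, had no IDR summit within 500 bp of its 5′ end. It had 1 IDR peak in an intron, 2666 bp inside the gene (chromosome III, 10905197 to 10905436, signal 264, rank 844), and 5 other pooled peaks inside the gene with signals from 18.8 to 55.6. Whether signal over either gene came from the endogenous locus or from the transgene was not tested.

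**Figure D4:**
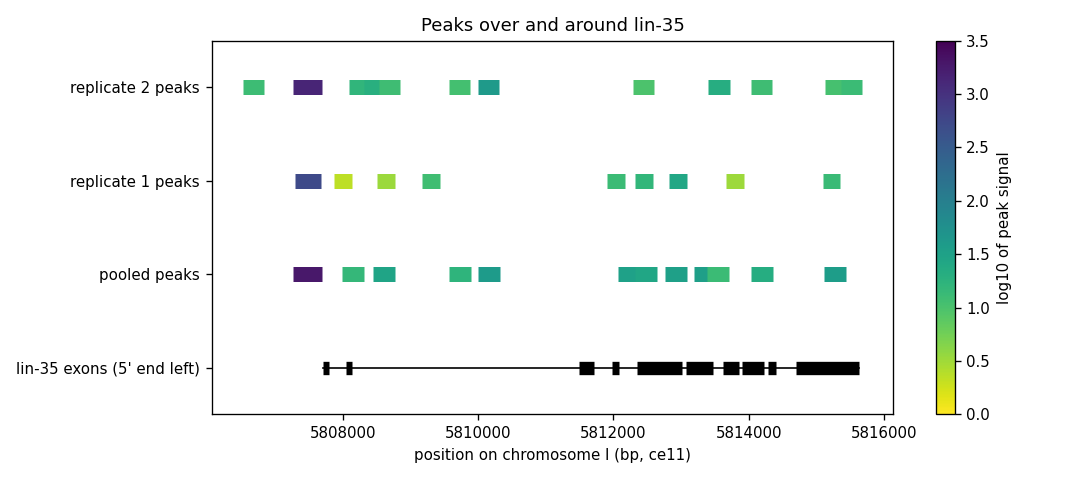
Peaks over lin-35 on chromosome I (position in bp, ce11), with exons in black, 1 row per peak list, and color for the log10 of the peak signal, to be compared only within a row. The promoter peak lies left of the first exon, and 11 weak pooled peaks lie inside the gene.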

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

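Of the tests in this part, those on the density of peaks in lin-35 and unc-119 as extra copies were chosen after the weak peaks had been seen, those on ribosomal protein and proteasome peaks apart after the pooled shares had been seen, the GC-stratified motif comparison was added after seeing the data, and the bound of 1 for both sequences in it was applied after its values were seen.

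Signal appeared on the mitochondrial chromosome, which entered no comparison: the list of replicate 1 held 26 mitochondrial peaks, with a median signal of 153 and ranks from 24 to 6935 among 23861, and the lists of replicate 2 and of the pooled data held 0.

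The E2F consensus and its reversed sequence were both more frequent at summits than 500 bp away. Among peaks at gene starts, and within bins of GC content, the common odds ratio for strong against weaker peaks stayed at 3.26 for TTSSCGC (95% interval 2.70 to 3.94) and 3.60 for CGCSSTT (2.83 to 4.59), which argues against GC content of the window as the whole cause. The criterion set before this comparison was run asked whether TTSSCGC exceeded its reversed sequence, and as it did not, that criterion alone would have kept GC content; it left out that GC content as the whole cause puts both odds ratios near 1. Whether the strong peaks prefer the E2F consensus itself stays open, since the intervals overlap. Beyond that preference, no biological explanation was tested.

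Ribosomal protein and proteasome promoters (86.4% and 75.8% bound) were bound about as often as DNA replication and mitosis promoters (85.0% and 75.4%) with the window of 500 bp, a likeness that was not tested and that was lost for ribosomal proteins within 250 bp (19.8% against 72.5% and 60.7%); with nearest starts only, 43 of 81 ribosomal protein, 30 of 40 DNA replication and 35 of 61 mitosis genes were bound. The E2F consensus lay at 10 of 92 peaks of the former and 47 of 80 of the latter (58.8%, Fisher's exact test, 2-sided, p = 1.82e-11), which argues against E2F sites as a reason shared by all these genes. Ribosomal protein peaks carried it at 3 of 67 (4.48%, Fisher's exact, p = 2.95e-13), and 76.1% of them had neither motif (p = 5.18e-13); over both sets 67.4% had neither, against 17.5% at replication and mitosis genes (p = 3.70e-11). Whether promoters that collect many factors may account for this stays open, since a lack of both motifs does not show how many factors a promoter collects. The tests on ribosomal protein and proteasome peaks apart also came after the pooled shares had been seen. For proteasome peaks E2F sites stay open too: 7 of 25 carried the E2F consensus, fewer than at replication and mitosis genes (Fisher's exact, p = 0.0110) but above the 16.1% of all bound genes. Neither motif lay at 11 of 25 proteasome peaks, more than at replication and mitosis genes (Fisher's exact, p = 0.0135) but below the 60.9% of all bound genes. No control precipitation was analysed here.

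Many weak peaks lie inside the lin-35 gene. The density of 1.39 pooled peaks per kb exceeded that of all 55 genes of similar length that had 1 of the 200 strongest promoter peaks (percentile 100, highest 1.21). In replicate 2 the density exceeded that of 98.2% of them. The same weak peaks made up the pattern under test, and extra copies in the transgene could also raise peaks that trail the promoter peak. This comparison therefore cannot decide whether the weak peaks trail a strong promoter peak. Among genes of similar length the lowest percentile of lin-35 and unc-119 over both replicate lists was 97.8, but as the weak peaks prompted this test, it restates them, and extra copies in the transgene stay open. Leaving out the first 500 bp of each gene, a definition also computed, gave a lowest percentile of 98.3. The number of transgene copies was not measured here.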

How the results depend on the processing

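The strength test with each shared peak counted once, the background of genes with any pooled peak and the GC-stratified motif tests were added after seeing the data. Of 229 alternative values for main results, 194 kept direction and side of the threshold (counts: stayed within 1.5 times) and 35 did not. Replicate overlap (58.9% to 81.3%), the share of peaks at gene starts (39.9% to 68.6%) and the E2F motif TTSSCGC (2.54 to 4.35 times) kept both under every alternative run, and the ratio of the reversed control CGCSSTT was 5.63. DREAM, DNA replication, mitosis, DNA repair, ribosomal protein and proteasome lists stayed higher, and collagens, chemoreceptors and homeobox and nuclear receptors lower, under all 9 alternatives. The DREAM list gave no finite odds ratio without candidate downstream operon genes (6 of 6 bound). Odds ratios ranged from 8.46 to 33.7 otherwise for DREAM, 25.7 to 83.1 for DNA replication, 11.5 to 37.7 for mitosis, 3.65 to 11.8 for DNA repair, 2.47 to 66.4 for ribosomal proteins, 10.2 to 43.4 for proteasome, 0.0590 to 0.312 for collagens, 0.0146 to 0.0528 for chemoreceptors and 0.187 to 0.480 for homeobox and nuclear receptors. For the changes below the cause was not tested. No paired analysis was possible because there was 1 group. Depth is unknown, so what it limits cannot be given.

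With the stronger 1919 peaks, rho was 0.834 and the X ratio 0.595; odds ratios were 4.30 for synMuv, 2.51 for small RNA, 0.332 for meiosis, 0.604 for histones, 0.965 for neuron markers and 0.293 for sperm proteins. There 0 lists passed the strength test (permutation, adjusted), and rank differences were 115.5 for synMuv, 206.5 for cell cycle regulators and for small RNA, 141 for proteasome and 387 for collagens. Against chromosome length the ratio was 0.715 for X, 1.04 for II and 0.954 for IV.

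Within 250 bp, odds ratios were 1.72 for cell cycle regulators, 0.999 for P granule genes, 2.21 for histones, 0.605 for neuron, 0.416 for muscle and 0.285 for sperm proteins. Within 1000 bp they were 4.29 for synMuv, 2.57 for small RNA, 0.996 for neuron and 0.517 for sperm proteins, with rank differences of -188 for meiosis and 161 for chemoreceptors. With nearest starts only they were 2.195 for cell cycle regulators and 0.241 for sperm proteins. Against genes with any pooled peak they were 0.956 for small RNA, 0.737 for neuron, 0.537 for muscle and 0.313 for sperm proteins.

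The ratio of the CHR motif was 0.995 in the stronger peaks and 0.979 against weaker pooled peaks, and its odds ratio 2.24 (0.874 for the reversed sequence) at gene starts with GC strata, where the motif was already more frequent without them (30.7% against 25.5%). Leaving out 1 replicate at a time, the X ratio ranged from 0.915 to 0.928, that of IV from 0.980 to 1.02, the odds ratio for meiosis from 0.424 to 1.23, that for sperm proteins from 0.181 to 0.390, and 1 to 3 lists passed the strength test.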

Other observations

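The gene families, short sequences and noncoding genes below were chosen after the data had been seen.

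Among 240 families of at least 8 genes with a shared symbol stem, 29 were bound more often and 33 less often than other genes, families that overlap those lists included (Fisher's exact test, 2-sided, adjusted over families). Nucleoporin (npp) genes were bound at 20 of 26 (odds ratio 21.3, Fisher's exact, adjusted p = 3.70e-11), with npp-3 (signal 1584, in the peak it shares with top-2) and npp-19 (signal 1271) strongest, and translation initiation factor (eif) genes at 18 of 25 (odds ratio 16.4, adjusted p = 1.84e-09), with eif-3.C at rank 16. Mitochondrial ribosomal protein genes were bound at 20 of 41 (mrpl, Fisher's exact, adjusted p = 2.06e-06) and 15 of 29 (mrps, adjusted p = 1.87e-05), Integrator subunit (ints) genes at 9 of 11 (adjusted p = 1.25e-05), RNA polymerase II subunit (rpb) genes at 8 of 11 (adjusted p = 0.000159), with rpb-11 at rank 18, and chaperonin (cct) genes at 7 of 8 (adjusted p = 8.15e-05). C-type lectin (clec) genes were bound at 4 of 240 (odds ratio 0.106, Fisher's exact, adjusted p = 2.42e-09), cytochrome P450 (cyp) genes at 1 of 74 (adjusted p = 0.00324) and neuropeptide-like (nlp) genes at 1 of 71 (adjusted p = 0.00413).

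Some peaks lay at noncoding genes. Within 500 bp of a tRNA gene start lay 155 IDR summits (4.04%, against 0.487% after shifts, 8.29 times), 124 of them among the 1702 peaks with no protein-coding start nearby, and 100 lay near snoRNA genes (7.29 times, permutation test, 1-sided, adjusted p = 0.00120 for both). The 15363 piRNA genes showed no excess (88 summits, 0.497 times, permutation test, 1-sided, p = 1).

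Of the sequences of 7 bp found at 200 or more summits, those with the highest ratio to windows 500 bp away were CGCAGAC (264 summits, 16.5 times), GAGAGAC (370, 14.8 times), CTGCGTC (520, 12.7 times) and GAGACGC (518, 12.3 times), windows of lower GC content. Against weaker peaks at gene starts their ratios were 3.14, 2.47, 2.81 and 3.20, and that of AACGCGC, the highest of the 20 sequences listed, was 14.9 (10.7% against 0.717%). In DNA replication and mitosis peaks TTSSCGC was found at 47 of 80 and its reversed sequence at 11 of 80, whereas in ribosomal protein peaks the reversed sequence was found at 9 of 67 and TTSSCGC at 3.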
